A study of Mus musculus with 30 samples.

How the data were processed

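The series profiled sorted mouse B cells on Affymetrix Mouse Gene ST arrays. The mice were CeGFP BALB/c animals, in which an IRES-GFP cassette sits in the 3' untranslated region of the membrane IgE transcript, so that GFP marks cells whose epsilon locus has been rearranged. They were infected with the parasitic worm Nippostrongylus brasiliensis, and mesenteric lymph node cells were sorted on day 10. GFP is carried by IgE cells and also by IgG1 cells with a rearrangement to the epsilon locus on the chromosome that is not expressed, per the labels. Per the labels' protocols, germinal centre (GC) cells were sorted as B220+ CD95+ CD138-, plasma cells (PC) as CD95+ CD138+, and naive cells as B220+ CD95- CD138- without surface IgG1 or IgE. Dark zone (DZ) cells were CXCR4 high and CD86 low, and light zone (LZ) cells CXCR4 low and CD86 high. Each sample was a pool of 3 mice from an independent sort.

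Per the labels' protocols, 2 ng of total RNA was amplified by single-primer isothermal amplification and 5 ug of cDNA was labelled with biotin. The deposited values are on the log2 scale and came from robust multi-array averaging (RMA), which subtracts background, quantile-normalizes the arrays and summarizes the probes, in R 2.15.2, per the submitters' processing notes. Whether the arrays of both experiments were normalized in 1 run is not given in the sources used here, so no level was set across the experiments. Neither a hybridisation batch nor a date was given in the sources used here, so a batch could not be tested. Normalization to a common distribution hides any change in total RNA per cell, and values near the floor compress fold changes of dim genes. The number of arrays, 2 to 4 per group, limits the precision. Amplification from 2 ng may add spread between arrays, which cannot be separated here from spread between pools.

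The table held 34760 probe sets on 30 arrays. The platform annotation gave 1 gene symbol for 21640 probe sets, several for 1321 and none for 11799. Of the single-symbol probe sets, 21553 had a gene ID in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Probe sets with several symbols or none were left out. Each of the 19937 genes was represented by its probe set with the highest mean over the 30 arrays. A gene was tested if it lay above the median of the array on at least 2 arrays of the first experiment or 3 arrays of the second, which left 12098 and 11050 genes. The epsilon and gamma-1 heavy chain genes had no probe set with a single symbol and were not analysed here.

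The first experiment had 6 groups (18 arrays). They were GFP-negative IgG1 GC (3), GFP-positive IgG1 GC (3), IgE GC (3), GFP-positive IgG1 PC (2), IgE PC (4) and naive cells (3). The second had DZ and LZ IgG1 GC cells, each GFP-positive and GFP-negative, with 3 arrays per group. Linear models were fitted to all arrays of an experiment with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups shared 1 estimate of the spread. There were 12 comparisons, of which 2 were interactions. P-values were adjusted over all genes tested by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Errors of group levels are SD over arrays, and errors of fold changes are SE from the fit. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.

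Gene lists were tested with camera in limma at its preset correlation of 0.01 between genes, and again with the correlation estimated from the residuals. Adjusted p-values of lists are over the 26 lists of a comparison. The lists, with 422 genes, were written from textbook knowledge. They covered the germinal centre programme, the plasma cell programme, the unfolded protein response and secretory pathway, B cell identity, MHC class II antigen presentation, B cell receptor signalling, dark zone genes, light zone genes, G1/S and DNA replication, and G2/M and mitosis. Further lists held the BCL2 family and apoptosis, the NF-kB and CD40 response, the IL-4 and IL-21 response, migration and homing receptors, hypermutation with class switching and DNA repair, MYC targets and ribosome biogenesis, glycolysis, oxidative phosphorylation, immunoglobulin constant regions, and immediate early and stress genes. Marker lists covered T cells, natural killer cells, basophils and mast cells, macrophages and dendritic cells, neutrophils and eosinophils, and stromal and endothelial cells. Some genes were in several lists, so results of such lists are not separate. Plk1, Cdc20, Ccnb2 and Aurka were in the dark zone and G2/M lists, and Polh in the dark zone and hypermutation lists. Cd83, Cd40, Rel, Nfkbia, Nfkbie and Traf1 were in the light zone and NF-kB lists. The dark zone and migration lists held Cxcr4, and the light zone and MHC class II lists Cd86, both sort markers of the zones. The germinal centre list held the sort marker Fas and the plasma cell list Sdc1. Of the list genes, 342 were tested in the first experiment and 321 in the second. Zone signatures were the up to 200 genes with the largest fold among those called in each direction between DZ and LZ, and they were tested on the first experiment, whose arrays are separate.

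Genes were named by a fixed rule. In each comparison these were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, up to 4 called members of each list, and a fixed set of B cell genes. Non-overlap was not required in the interactions, where it has no simple meaning. Not every gene that met the rule is mentioned. Fas, Sdc1 and Ptprc encode proteins used in the sort, so their levels only check the labels. The same holds for Cxcr4 and Cd86 only between the sorted zones. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Those alternatives were no filter or a 75th percentile filter, averaged probe sets, a further quantile normalization, fits on only the compared groups, the replicate number as a block, a trended and robust variance model, a minimum of 2-fold, and each array left out in turn. Array weights, a fit to only the 9 GC arrays, a fit without 2 arrays that stood apart from the others of their groups, exact permutation tests on list means and the repeat of the list tests without single arrays or with the block were chosen after seeing the data.

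Replicate numbers from the labels were checked for pairing through the correlation of deviations from the group means. GFP-positive and GFP-negative IgG1 GC arrays of equal number correlated at 0.109 to 0.154, above the limit of 0.1 in every pair, and each number matched best with itself. No other groups that were compared passed that limit in every pair. Each number also matched best with itself between IgE GC and GFP-negative IgG1 GC arrays (0.095 to 0.14). The same held in most pairs of zone groups, such as GFP-positive DZ with GFP-positive LZ (0.068 to 0.095). Weaker pairing below the limit thus stayed possible there, and the main fits took no account of it. On simulated data with 200 changed genes, the fit for DZ against LZ (11050 genes) recovered 44% of 1.5-fold, 88% of 2-fold and 100% of 4-fold changes, with 5, 9 and 8 false calls. For IgE GC against GFP-positive IgG1 GC (12098 genes) the recovery was 1%, 48.5% and 94%, with 1, 8 and 9 false calls. For IgE PC against IgG1 PC (12098 genes) it was 0%, 45.5% and 90%, with 0, 6 and 8 false calls. The simulated noise was normal and independent between genes and arrays, with 1 spread per gene for all groups. Real groups differed in their spread, with the lowest correlations among naive and IgG1 PC arrays. The rates therefore check the fit under its own assumptions and need not hold for the real arrays.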

Results

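Transcript levels were measured on 30 arrays of sorted mesenteric lymph node B cells from worm-infected CeGFP mice. The first experiment compared IgE-expressing and IgG1-expressing GC cells and plasma cells with naive B cells, on 18 arrays. The second compared DZ and LZ cells of the IgG1 germinal centre, on 12 arrays. All values are log2 signals. Array medians lay between 5.28 and 5.47, and arrays of 1 group correlated at 0.891 to 0.975, lowest among the naive arrays (0.891 to 0.927). Naive replicate 1 (mean correlation with its group 0.892) and GFP-positive IgG1 GC replicate 3 (0.949) each correlated less with their group than the other 2 arrays of it did (0.909 and 0.910, and 0.962 each), and are called the 2 arrays that stood apart. The 2 IgG1 PC arrays correlated at 0.934.

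Entry into the germinal centre was first described against naive B cells. GC cells of both isotypes were marked by cell division and by the germinal centre programme. Mki67, a marker of cycling cells, was at 10.97 ± 0.02 in IgE GC and 10.73 ± 0.07 in GFP-positive IgG1 GC cells against 4.91 ± 0.05 in naive cells (SD, n = 3 each), log2 differences of 6.06 and 5.82 (SE 0.12 each). Mybl1, a GC transcription factor, was higher by 6.48 and 6.39, and Gcsam, a germinal centre signalling adaptor, by 5.94 and 5.36. Bcl6, the repressor that establishes the GC fate, was already at 9.39 ± 0.49 in naive cells and higher by 1.55 and 1.64 in GC cells (adjusted p = 0.00641 and adjusted p = 0.0048). Without the 2 arrays that stood apart the IgG1 value for Bcl6 was 1.36 and not called. Genes that fell included Ptpn22, a phosphatase that restrains antigen receptor signalling (-4.66 in IgE and -4.84 in IgG1 GC cells), the egress receptor S1pr1 (-2.85 and -3.43), the chemokine receptor Ccr6 (-3.16 and -2.83) and the survival gene Bcl2 (-2.60 and -2.81).

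In all, 3230 genes differed between IgE GC and naive cells at an adjusted p under 0.05 in limma (2335 higher, 895 lower), and 2813 between GFP-positive IgG1 GC and naive cells (2035 higher, 778 lower). After a further quantile normalization the split was 1836 higher and 1113 lower for IgE and 1735 and 991 for IgG1. With only the groups compared in the fit the counts were 2049 and 1524. All 28 tested G2/M genes rose in both isotypes, and so did 25 of 25 G1/S genes in IgE and 24 of 25 in IgG1 cells (25 adjusted over the list alone). For example, Bub1, a mitotic checkpoint kinase, rose by 5.18 and 5.04, and Mcm3, part of the replicative helicase, by 3.71 and 3.63. Of the germinal centre programme, 12 of 13 genes rose in both, among them the sort marker Fas (3.60 and 3.53). Of the hypermutation and repair list, 11 of 16 rose in IgE and 12 in IgG1 cells (14 in each adjusted over the list alone), including the translesion polymerase Polh (3.58 and 3.36). The dark zone list had 5 of 7 genes higher, among them Ccnb2, Plk1 and Aurka of the G2/M list. In both isotypes 1 was lower, Cxcr4 (-0.57 and -0.69), which was a sort marker only in the second experiment. Migration receptors fell in 10 of 16 cases in IgE and 9 in IgG1 cells, with 3 higher in each. With an estimated correlation these list calls held, at an adjusted p of 0.045 or less.

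Metabolic and secretory lists also rose, though not with an estimated correlation. Oxidative phosphorylation genes were higher for 14 of 19 (IgE, median 0.98) and 13 of 19 (IgG1, median 0.95), with adjusted p = 0.076 and adjusted p = 0.089 with an estimated correlation. Glycolysis genes such as Tpi1 (2.51 and 2.43) were higher for 8 and 7 of 11, with adjusted p = 0.18 and adjusted p = 0.16 with an estimated correlation. The unfolded protein response and secretory list had 26 of 37 genes higher in IgE and 15 of 37 in IgG1 cells. Its camera calls (adjusted p = 1.3e-07 and adjusted p = 0.0013) became adjusted p = 0.16 and adjusted p = 0.35 with an estimated correlation. MYC targets had 7 of 20 genes higher in IgG1 cells (adjusted p = 0.0025, and adjusted p = 0.31 with an estimated correlation). In IgE cells 6 rose, but the list call (adjusted p = 0.049) was lost without any 1 of IgE GC replicates 2 or 3 or naive replicates 1 or 3 (adjusted p 0.054 to 0.093), after quantile normalization (0.15) and with an estimated correlation (adjusted p = 0.41). The NF-kB and CD40 response list was called lower in IgE cells with 4 of 14 genes lower and 2 higher (median -0.38, adjusted p = 0.03, and adjusted p = 0.29 with an estimated correlation), and without naive replicate 2 the first of these was 0.1. In IgG1 cells the median was -0.35 and the list was not called (adjusted p = 0.2). No camera call against naive cells was made for B cell identity, MHC class II, B cell receptor signalling, light zone, BCL2 family, IL-4 and IL-21 response, immunoglobulin constant region, immediate early or plasma cell lists in either isotype. Several of these lists passed in other settings. B cell identity passed as lower without naive replicate 1 in IgE (0.041) and IgG1 cells (0.032) and in IgG1 cells without GFP-positive replicate 1 (0.027). In IgE cells the plasma cell list passed as higher without IgE GC replicate 1 or 2 or naive replicate 1 (adjusted p 0.019 to 0.034), and the light zone list as lower without naive replicate 1 (0.029). After quantile normalization identity and receptor signalling passed as lower in both isotypes (0.0084 to 0.021), and in IgE cells the plasma cell (0.021) and light zone lists (0.029) passed too. In IgG1 cells the plasma cell list had a median of -0.02 with a mean of 0.42, and the light zone list -0.07 with 0.04. In IgE cells the IL-4 and IL-21 list had a median of 0.23 but was tested as lower, and the BCL2 family had -0.02 with a mean of 0.14 (-0.03 and 0.11 in IgG1 cells).

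Markers of other cell types differed in the same comparisons. The macrophage and dendritic cell list fell in IgE GC (4 of 8 genes, adjusted p = 0.015, and adjusted p = 0.076 with an estimated correlation) and in IgG1 GC cells (4 of 8, adjusted p = 0.0015, and adjusted p = 0.028 with an estimated correlation). Tyrobp, an adaptor of myeloid and natural killer receptors, was at 8.43 ± 0.28 in naive cells against 5.65 ± 0.31 in IgE and 5.42 ± 0.10 in IgG1 GC cells (SD, n = 3 each). For Siglech, a plasmacytoid dendritic cell marker, the log2 differences were -1.73 and -1.70. T cell markers were lower in IgG1 GC cells (4 of 9, adjusted p = 0.0034, and adjusted p = 0.09 with an estimated correlation). In IgE GC cells 2 of 9 were lower, with adjusted p = 0.067, which passed without IgE GC replicate 1 (0.026) or naive replicate 3 (0.044). The stromal list was lower in IgE GC cells (2 of 9, adjusted p = 0.02, 0.072 after quantile normalization, and adjusted p = 0.29 with an estimated correlation). In IgG1 cells it had adjusted p = 0.056, which passed without naive replicate 2 (0.02) or GFP-positive replicate 3 (0.032). Natural killer, basophil and neutrophil lists were not called in either.

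The second experiment addressed what separates dark zone from light zone cells. Plk1, a mitotic kinase, was at 9.53 ± 0.35 in DZ against 8.19 ± 0.37 in LZ cells (SD, n = 6 each), a log2 difference of 1.34 (SE 0.18, adjusted p = 0.000805). Hmces, a sensor of abasic DNA sites, was at 10.51 ± 0.13 against 9.08 ± 0.29 (1.43, SE 0.11, adjusted p = 4.2e-05). The repair ligase Lig4 was higher by 1.29 and Polh by 0.99. LZ cells had more Serpinb1a, a protease inhibitor (-2.51, SE 0.23), the calcium channel gene Ryr2 (7.94 ± 0.24 against 5.80 ± 0.13, -2.14), Egr2 and Nr4a1, both induced by antigen receptor signals (-1.56 and -1.29), and the activation markers Cd69 (-1.29) and Cd83 (-1.07). Of the sort markers, Cd86 differed by -1.10 (adjusted p = 9.48e-05) and Cxcr4 by 0.31 (adjusted p = 0.127). Bcl6 (0.15) and Pax5 (-0.01) were not called.

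Between the zones 764 genes differed in limma, 433 higher in DZ and 331 higher in LZ cells, of which 102 changed at least 2-fold. After a further quantile normalization the split was 356 and 410. Leaving out GFP-positive LZ replicate 2 lowered the count to 479. Of the G2/M list 20 of 28 genes were higher in DZ cells (26 adjusted over the list alone), with Cenpf at 1.42 and Cdc20 at 1.25. That list's camera call (adjusted p = 8.7e-25) gave adjusted p = 0.075 with an estimated correlation. From the dark zone list 4 of 7 genes were higher (6 over the list alone; adjusted p = 0.0077 with an estimated correlation). These were Plk1, Cdc20 and Ccnb2, also of the G2/M list, and Polh, also of the hypermutation list. From the light zone list, which holds the sort marker Cd86, 18 of 23 were lower (21 over the list alone; adjusted p = 0.017 with an estimated correlation). The NF-kB and CD40 response had 10 of 14 genes lower (13 over the list alone; adjusted p = 0.016 with an estimated correlation), among them the feedback inhibitor Nfkbia (-0.79) and the chemokine Ccl22 (-0.85). The transcription factors Irf4 (-1.28) and Batf (-0.95), of the light zone list, were lower in DZ cells as well.

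The other list calls between the zones were made only at the preset correlation. Oxidative phosphorylation genes were higher in DZ cells in 4 of 19 cases (15 over the list alone), with Sdhb of respiratory complex II at 0.77 (adjusted p = 0.1 with an estimated correlation). G1/S genes were higher in 4 of 25 (7 over the list alone; adjusted p = 0.13 with an estimated correlation). Lower in DZ cells were 4 of 11 MHC class II genes (5 over the list alone), with the class II activator Ciita at -0.69 (adjusted p = 0.087 with an estimated correlation). Among these 4 was the sort marker Cd86 (-1.10), which only checks the labels. B cell identity had 5 of 20 genes lower and 1 higher, among them the complement receptor Cr2 (-0.99) and the CD23 gene Fcer2a (-0.96), and B cell receptor signalling had 5 of 24 lower. Both gave adjusted p = 0.22 with an estimated correlation, as did the IL-4 and IL-21 list (3 of 13 lower, 1 higher). Higher were 5 of 13 germinal centre genes (adjusted p = 0.28 with an estimated correlation), such as Gcsam (1.03) and Nuggc (0.72), and 2 of 16 hypermutation genes (adjusted p = 0.25 with an estimated correlation). The plasma cell list (4 of 9 higher, Irf4 lower, 5 higher over the list alone; adjusted p = 0.041) was lost without any 1 of 5 arrays: GFP-positive LZ replicate 2, GFP-negative DZ replicate 2, GFP-negative LZ replicate 2, and replicate 3 of either DZ group (adjusted p 0.061 to 0.092), and after quantile normalization (0.053; adjusted p = 0.25 with an estimated correlation). The immediate early list (1 of 9 lower; adjusted p = 0.044) was lost without any 1 of 7 arrays, replicates 1 and 2 of both DZ groups, replicates 2 and 3 of GFP-positive LZ and replicate 2 of GFP-negative LZ (adjusted p 0.05 to 0.1; adjusted p = 0.35 with an estimated correlation). Not called were the unfolded protein response, BCL2 family, migration, MYC target, glycolysis and immunoglobulin lists and the 6 lists of other cell types. Of these, glycolysis passed without GFP-negative DZ replicate 1 (0.047), and T cell markers passed as lower without GFP-positive DZ replicate 1 (0.049) or GFP-negative LZ replicate 2 (0.021). The secretory list had a median of -0.03 with a mean of 0.01, and macrophage markers 0.03 with -0.06.

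**Figure D1:**
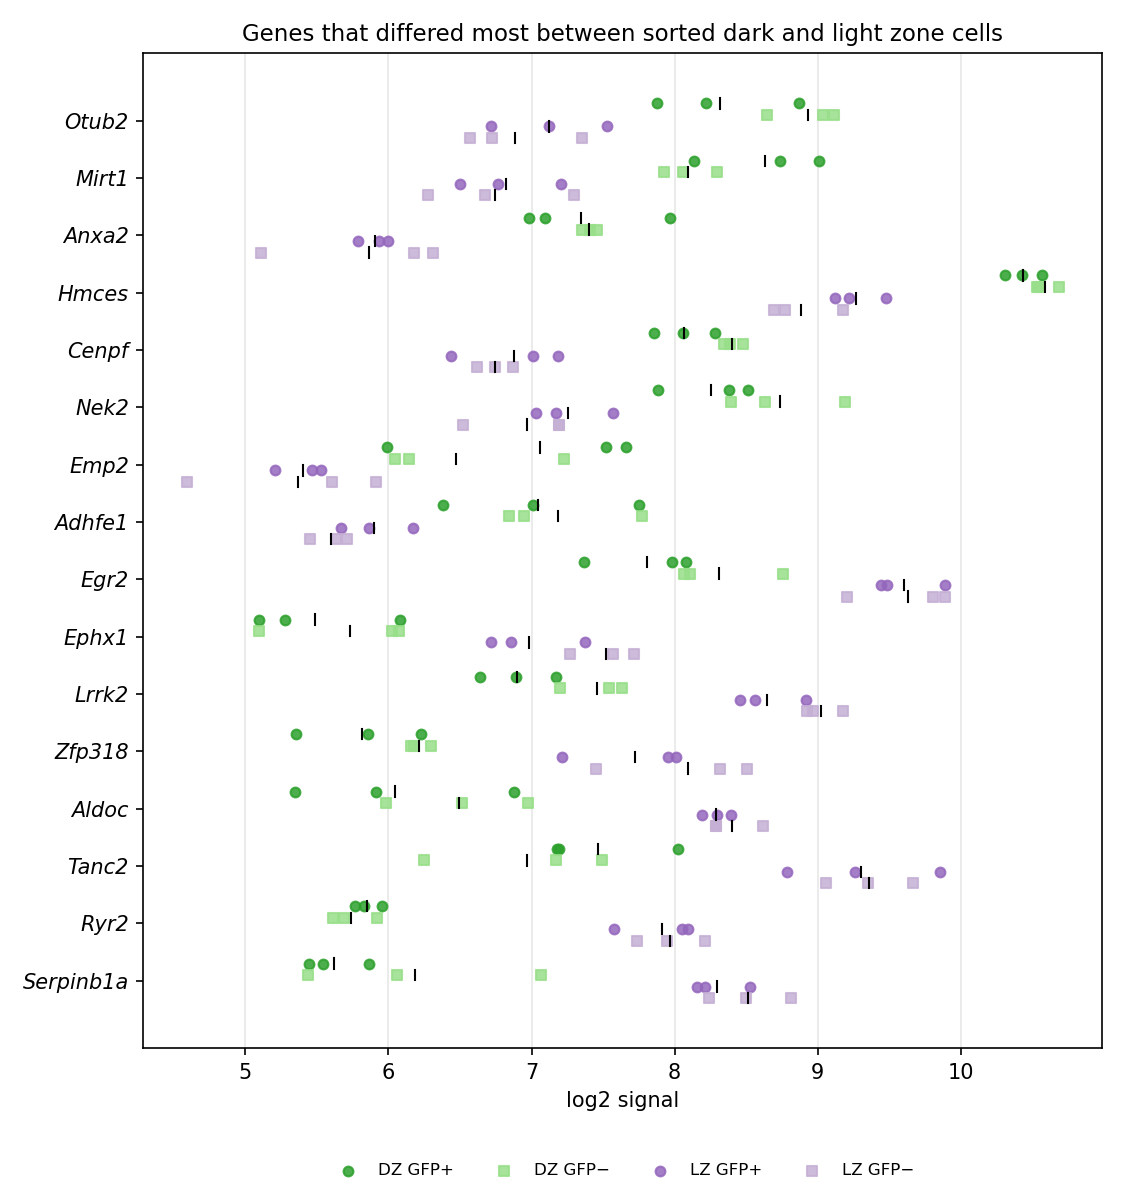
Log2 signal (horizontal axis) of the 8 genes most raised and the 8 most lowered in DZ against LZ cells (vertical axis), in DZ and LZ cells, each GFP-positive and GFP-negative by colour and shape, with 1 marker per array (n = 3 per group) and a tick at each group mean. Hmces had a mean of 10.51 over the DZ and 9.08 over the LZ arrays, and Ryr2 of 5.80 and 7.94.

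Whether GFP, which marks a rearrangement to the epsilon locus in IgG1 cells, went with other transcripts was tested in the sorted zones and in unseparated GC cells. In the zones Irf4, a factor that drives plasma cell differentiation at high dose, was at 6.34 ± 0.92 in GFP-positive and 6.81 ± 0.80 in GFP-negative cells (SD, n = 6 each; -0.47, SE 0.26, adjusted p = 0.941). These SD span both zones, between which Irf4 differed by -1.28, so they are not the spread behind the test. Xbp1, which drives secretory expansion, differed by 0.11, Bcl6 by -0.01 and Myc by -0.12. Among unseparated GC cells, Irf4 was at 6.59 ± 0.38 in GFP-positive and 7.39 ± 0.53 in GFP-negative cells (SD, n = 3 each; -0.80, adjusted p = 1), and Prdm1, the plasma cell repressor, differed by -0.43. No gene passed in either comparison in limma, with 519 and 265 genes at an unadjusted p under 0.05 (552 and 605 expected by chance). With only the groups compared in the fit 1 gene passed between the unseparated cells. No list was called in the zones (smallest adjusted p 0.24). Without GFP-negative LZ replicate 3, B cell identity and B cell receptor signalling passed as lower in GFP-positive cells (adjusted p = 0.02 each), and identity also after quantile normalization (0.016). T cell markers had a median of 0.02 with a mean of -0.06.

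Between unseparated GFP-positive and GFP-negative IgG1 GC cells, plasma cell, B cell identity, B cell receptor signalling and immunoglobulin lists had the smallest adjusted p (0.063 each), with medians of -0.21, -0.16, -0.14 and -0.40. With the replicate number as a block, which paired these arrays, the receptor signalling list passed (adjusted p = 0.041, 3 of 24 genes above 0). After quantile normalization all 4 passed as lower (adjusted p 0.042 to 0.044). Leaving out single arrays also moved these calls. Without GFP-negative replicate 3 all 4 lists and the unfolded protein response passed as lower (adjusted p 0.0074 to 0.034), without GFP-positive replicate 1 B cell identity and receptor signalling passed (0.016 and 0.0063), without GFP-positive replicate 3 the immunoglobulin list (0.03), and without GFP-negative replicate 1 G2/M (0.044). Every list gave an adjusted p of 0.67 or more with an estimated correlation. Macrophage markers had a median of 0.09 with a mean of -0.09.

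The difference between the zones was also compared between GFP-positive and GFP-negative cells. No gene passed that interaction in limma (543 at an unadjusted p under 0.05), with Irf4 at -0.67, Xbp1 at -0.50 and Bcl6 at -0.27. All 28 G2/M genes had a smaller DZ excess in GFP-positive cells (median -0.41, adjusted p = 4.4e-05), as did 21 of 25 G1/S genes (-0.29, adjusted p = 0.0033) and all 7 dark zone genes (-0.51, adjusted p = 0.015). With an estimated correlation the first pair gave adjusted p = 0.97 and the dark zone list adjusted p = 0.32. The dark zone list is not separate from G2/M here, since Plk1, Cdc20, Ccnb2 and Aurka are in both. The dark zone call was lost without GFP-positive LZ replicate 2 (0.066) or GFP-positive DZ replicate 3 (0.079). MYC target and glycolysis lists passed without GFP-negative DZ replicate 2 (0.029 and 0.0062), and NF-kB without GFP-positive DZ replicate 1 (0.023) or GFP-negative DZ replicate 3 (0.045).

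The stated purpose of the first experiment was the comparison of IgE with IgG1 B cells. In the germinal centre, Xbp1 was at 9.33 ± 0.36 in IgE and 8.81 ± 0.34 in GFP-positive IgG1 cells (SD, n = 3 each), a log2 difference of 0.52 (SE 0.26, adjusted p = 1). Prdm1 was at 5.53 ± 0.89 against 4.84 ± 0.05 (0.68) and Irf4 at 7.25 ± 0.48 against 6.59 ± 0.38 (0.66). The GC regulator Bcl6 (10.94 against 11.03) and the B cell factor Pax5 (11.11 against 11.09) were near equal, and the growth regulator Myc was at 9.10 ± 0.11 against 9.59 ± 0.11 (-0.49). Against GFP-negative IgG1 cells the differences were 0.46 for Xbp1, 0.25 for Prdm1, -0.14 for Irf4, -0.30 for Cd83 and -0.32 for Myc. None of these differences passed the test. No gene passed in either comparison in limma, with 264 genes at an unadjusted p under 0.05 against GFP-positive and 205 against GFP-negative cells. Chance alone would give 605 in each, so both counts lay below it. Against GFP-positive cells the SE for Bcl6 was 0.38 with group SD of 0.03 and 0.07, and for Prdm1 0.31 with 0.89 and 0.05. Whether the spread shared by all groups was too large for the GC cells was not tested. With array weights 1 gene passed against GFP-negative cells.

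At the preset correlation, but not with an estimated one, lists of plasma cell genes were called in IgE GC cells. The plasma cell list was higher than in GFP-positive IgG1 cells (13 of 14 genes above 0, median 0.48, adjusted p = 4.9e-08) and than in GFP-negative ones (12 of 14, median 0.26, adjusted p = 0.0025). The unfolded protein response and secretory list was higher against both (34 of 37 genes above 0 in each, medians 0.28 and 0.18, adjusted p = 1.5e-12 and adjusted p = 1.7e-06). With an estimated correlation these became adjusted p = 0.16 and adjusted p = 0.26 for the plasma cell list, and adjusted p = 0.19 and adjusted p = 0.26 for the secretory list. IgE GC replicate 3 carried much of it. Without that array the plasma cell median was 0.33 (adjusted p = 0.0026) against GFP-positive and 0.13 (adjusted p = 0.56) against GFP-negative cells, and the secretory median 0.20 (adjusted p = 8.8e-05) and 0.07 (adjusted p = 0.072). No member of either list passed alone, also when adjusted over the list alone. Macrophage and dendritic cell markers were also higher on average, with a list mean of 5.93 ± 0.12 in IgE, 5.66 ± 0.06 in GFP-positive and 5.75 ± 0.14 in GFP-negative IgG1 cells (SD, n = 3 each), although camera made no call (adjusted p = 0.13, with 1 of 8 genes higher over the list alone, and adjusted p = 0.098). In a fit of the 9 GC arrays it did against GFP-positive cells (0.03). T cell markers were called higher (medians 0.19 and 0.13, adjusted p = 0.01 and adjusted p = 0.0025; adjusted p = 0.29 and adjusted p = 0.15 with an estimated correlation). The first of these calls was lost without GFP-positive replicate 1 (0.25) and in the fit of the 9 GC arrays (0.07), and both without IgE GC replicate 1 (0.36 and 0.16).

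The NF-kB and CD40 list was called lower in IgE GC cells at the preset correlation, with 3 of 14 genes above 0 against GFP-positive (median -0.14, adjusted p = 0.0028) and 2 of 14 against GFP-negative cells (-0.26, adjusted p = 2.4e-06). The light zone list, which shares genes with the NF-kB list, had 6 of 23 genes above 0 (-0.17, adjusted p = 0.0076) and 3 of 23 (-0.30, adjusted p = 2.4e-06). With an estimated correlation these gave adjusted p = 0.29 and adjusted p = 0.41 against GFP-positive and adjusted p = 0.13 for both against GFP-negative cells. Against GFP-negative cells both calls stood whichever array was left out. Against GFP-positive cells both were lost without GFP-positive replicate 1 (0.063 and 0.25), and the light zone call also without IgE GC replicate 2 (0.088) or the 2 arrays that stood apart (0.051). Adjusted over the list alone, 1 NF-kB gene was lower against GFP-negative cells. The MYC target list was called lower in both comparisons, with no member called (medians -0.16 and -0.14, adjusted p = 0.007 and adjusted p = 0.0049). With an estimated correlation these gave adjusted p = 0.47 and adjusted p = 0.37. That list lost the call without IgE GC replicate 1 (0.1 and 0.057), GFP-positive replicate 2 (0.4) or GFP-negative replicate 3 (0.054).

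The G1/S list of replication genes was called higher in IgE GC cells against both at the preset correlation, although no member passed alone (24 and 22 of 25 above 0, medians 0.20 and 0.12, adjusted p = 0.00078 and adjusted p = 0.013). With an estimated correlation these gave adjusted p = 0.47 and adjusted p = 0.6. The second call was lost without IgE GC replicate 2 or 3 or GFP-negative replicate 1 (0.072 to 0.16). The G2/M list was called higher against GFP-positive cells, also without a member that passed alone (25 of 28 above 0, median 0.15, adjusted p = 0.0043, and adjusted p = 0.6 with an estimated correlation). That call was lost without IgE GC replicate 3 (0.06, adjusted p = 0.64) or GFP-positive replicate 3 (0.08, adjusted p = 0.057). Against GFP-negative cells G2/M was not called (median 0.06, adjusted p = 0.46) but passed as higher without IgE GC replicate 1 (median 0.19, adjusted p = 0.00058) or GFP-negative replicate 3 (median 0.18, adjusted p = 0.008). Against GFP-negative cells only, receptor signalling (5 of 24 above 0, -0.16, adjusted p = 0.00061), immunoglobulin (0 of 3, -0.57, adjusted p = 0.0017) and B cell identity lists (5 of 20, -0.09, adjusted p = 0.013) were called lower. With an estimated correlation they gave adjusted p = 0.19, adjusted p = 0.15 and adjusted p = 0.26. The identity call was lost without GFP-negative replicate 1 (0.16) or IgE GC replicate 3 (0.078). Some lists that were not called passed without 1 array. Against GFP-positive cells these were oxidative phosphorylation as higher without GFP-positive replicate 2 (0.0047) and glycolysis as lower without replicate 3 (0.032). Against GFP-negative cells they were MHC class II as lower without GFP-negative replicate 3 (0.038) or IgE GC replicate 2 (0.048), immediate early genes as lower without GFP-negative replicate 2 (0.018) or 3 (0.035) or IgE GC replicate 1 (0.0089), and oxidative phosphorylation as higher without IgE GC replicate 1 (0.03). Median, mean and test differed in sign against GFP-positive cells for B cell identity (median 0.04, mean 0.02, tested lower), glycolysis (0.08, -0.01, lower) and immunoglobulin (-0.13, 0.07, lower), none of them called, and against GFP-negative cells for migration (0.03, -0.05, lower). The germinal centre, dark zone, BCL2 family, IL-4 and IL-21, migration, hypermutation, natural killer, basophil, neutrophil and stromal lists were not called in either comparison.

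**Figure D2:**
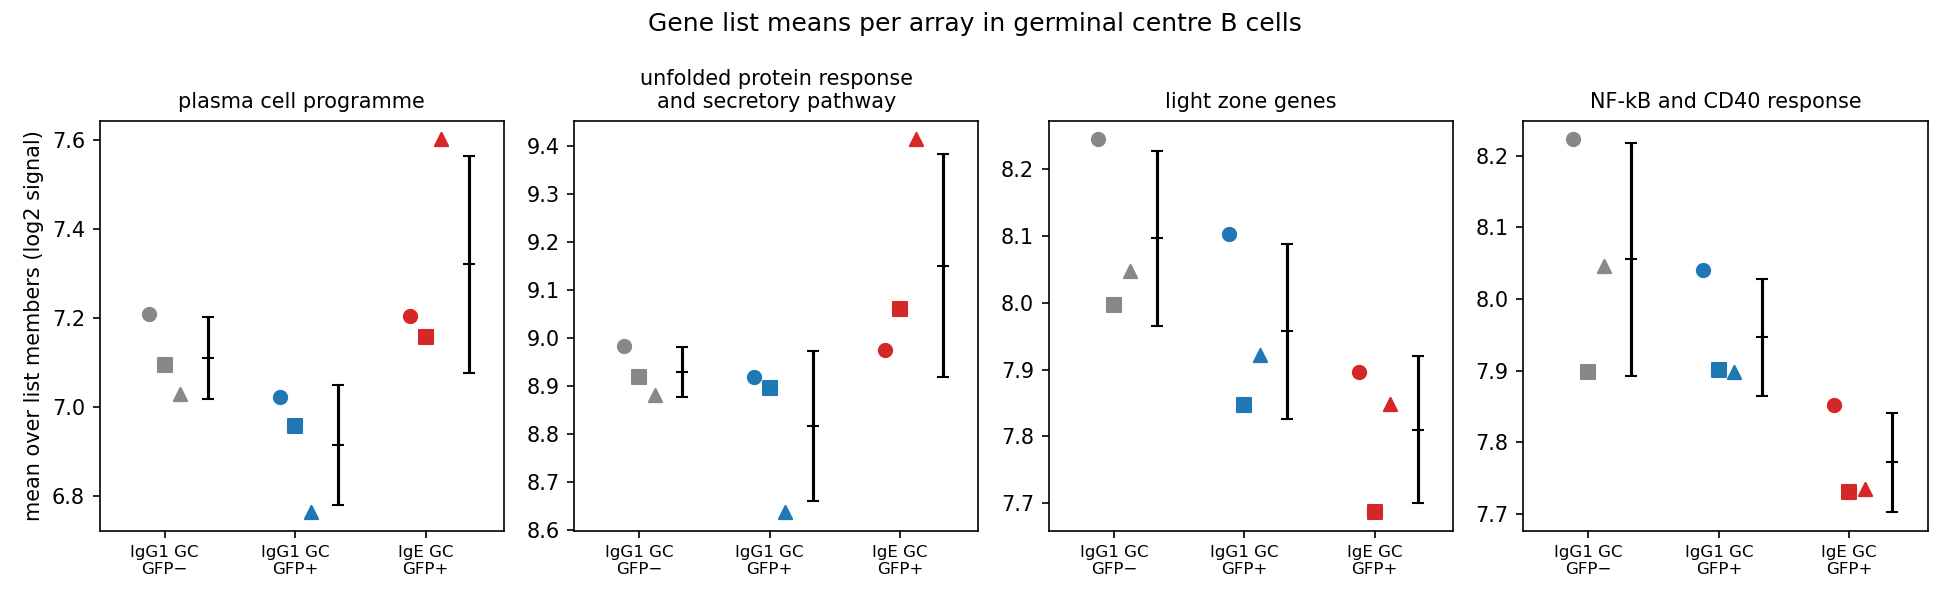
Mean log2 signal of the genes of 4 lists (vertical axis, 1 panel per list) on each array of the 3 GC groups (horizontal axis), with 1 marker per array, the marker shape giving the replicate number, and bars for the mean ± SD of the group (n = 3). For the plasma cell programme the group means were 7.32 in IgE, 6.91 in GFP-positive and 7.11 in GFP-negative IgG1 cells, and IgE GC replicate 3 was highest at 7.60.

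The zone signatures of the second experiment were then read out in the first. As a set the 200 DZ genes lay higher in IgE than in GFP-positive IgG1 GC cells, with 161 above 0 and a median of 0.19 (camera p of 9.99e-10 at the preset and 0.0388 with the estimated correlation). No single gene passed in that comparison. Of 10 splits of the same arrays, 3 gave a median as far from 0, the farthest other being -0.26. The splits thus did not set the shift apart from differences between arrays, though 10 are too few for a share under 0.05. With the genes of the cell cycle lists left out, a signature of again 200 genes had a median of 0.18. Genes outside those lists were kept whatever their role, so a part of cell division in the shift was not excluded. The p with the estimated correlation was above the threshold without IgE GC replicate 2 (0.144) or 3 (0.111), GFP-positive IgG1 GC replicate 1 (0.0814) or 3 (0.0939), or GFP-positive LZ replicate 1 (0.0607). It was also above it with the stricter filter (0.117), with only the compared groups (0.204) or the 9 GC arrays (0.153) in the fit, without the 2 arrays that stood apart (0.121), and with all genes past the threshold as the signature (0.0829). As a set the 200 LZ genes lay lower, with 75 above 0 and a median of -0.09 (6.57e-05, and 0.136 with the estimated correlation). For them 4 of 10 splits gave a median as far from 0, the farthest other being 0.18. The LZ value rested on few arrays: without GFP-positive IgG1 GC replicate 1 it was -0.003 (p of 0.203), without IgE GC replicate 2 -0.02, and without GFP-positive replicate 3 -0.13. Without the 2 arrays that stood apart it was also -0.13, with 53 above 0, and passed with the estimated correlation (0.0386). Against GFP-negative IgG1 cells the DZ median was 0.10 (9.96e-05, and 0.165 with the estimated correlation) and the LZ median -0.25, with 28 of 200 genes above 0 (1.06e-21, and 0.00234 with the estimated correlation).

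Plasma cells differed from GC cells in the secretory programme and in B cell identity, in both isotypes. Prdm1 was at 9.87 ± 0.10 in IgE PC (SD, n = 4) against 5.53 ± 0.89 in IgE GC (n = 3), a log2 difference of 4.35 (SE 0.29), and at 9.59 ± 0.03 in IgG1 PC (n = 2) against 4.84 ± 0.05 in GFP-positive IgG1 GC cells (n = 3), a difference of 4.74 (SE 0.35). Irf4 was higher by 3.67 and 4.24, Xbp1 by 1.93 and 2.79, and Bhlha15, which organises the secretory apparatus, by 4.68 and 5.48. The ectonucleotidase gene Entpd1 rose by 4.89 and 6.26. Bcl6 fell from 10.94 ± 0.03 to 5.07 ± 0.69 in IgE (-5.87) and by 6.05 on the log2 scale in IgG1 cells, and Spib (-5.81 and -6.45), Pax5 (-4.68 and -5.00) and Cd22 (-4.68 and -5.20) fell as well.

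In limma 2860 genes differed between IgE PC and IgE GC cells (1235 higher, 1625 lower) and 2593 between IgG1 PC and GFP-positive IgG1 GC cells (1007 higher, 1586 lower). Of the plasma cell list 13 of 14 genes rose in both, among them the sort marker Sdc1 (3.91 and 3.68). Of the secretory list 36 of 37 rose in IgE and 34 in IgG1 cells, for example Fkbp11, a foldase of the endoplasmic reticulum (4.38 and 5.04). B cell identity genes fell in 19 and 18 of 20 cases, germinal centre genes in 11 of 13 in both, and receptor signalling genes in 16 and 14 of 24. Those 5 lists held with an estimated correlation (adjusted p 0.012 or less). NF-kB genes fell in 6 of 14 cases in IgE (adjusted p = 0.16 with an estimated correlation) and in 9 of 14 in IgG1 cells (adjusted p = 0.016 with an estimated correlation), including Rel (-3.59 and -4.93). MHC class II fell in 8 of 12 in both (adjusted p = 0.095 and adjusted p = 0.062 with an estimated correlation), hypermutation genes in 8 of 16 in both (the same values, 0.095 and 0.062), and the 3 immunoglobulin genes rose in both (Ighm by 2.66 and 2.71; adjusted p = 0.055 with an estimated correlation in each). Of the light zone genes 7 and 10 of 23 fell and 3 rose in each (adjusted p = 0.31 and adjusted p = 0.11 with an estimated correlation). The IL-4 and IL-21 list had 5 of 13 genes lower in both, with Il21r at -2.77 and -4.09, but was not called (adjusted p = 0.11 and adjusted p = 0.071). In IgG1 cells it passed without GFP-positive GC replicate 1 (0.041) or PC replicate 2 (0.047), and glycolysis (3 of 11 lower) passed without GFP-positive GC replicate 3 (0.025) or after quantile normalization (0.043).

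The cell cycle lists were called lower in plasma cells at the preset correlation only. G2/M genes fell in 19 of 28 cases in IgE cells but in 4 of 28 in IgG1 cells, a share near that of all genes there (1586 of 12098), with the cytokinesis motor Kif23 at -1.84 and -1.85, and G1/S genes in 13 and 8 of 25. The camera calls (adjusted p = 4.6e-07 and adjusted p = 0.011 for G2/M, adjusted p = 2.4e-05 and adjusted p = 0.0061 for G1/S) were lost with an estimated correlation (adjusted p from 0.18 to 0.47). In IgG1 cells they were also lost without IgG1 PC replicate 1 (0.25 and 0.3). The dark zone list was lower in IgE cells (4 of 7, adjusted p = 0.029, and adjusted p = 0.18 with an estimated correlation), and that was lost without IgE GC replicate 3 (0.11). Among markers of other cells, the T cell gene Thy1 rose by 2.05 and 2.14 without the rest of its list in IgE cells (1 of 9 above 0, median -0.15, adjusted p = 0.84; 8 of 9 above 0 in IgG1 cells, median 0.26, adjusted p = 0.077), and the eosinophil granule gene Prg2 by 2.12 and 2.62. Outside the lists, the T cell receptor gene Trav14-1 had the largest rise of the named genes in IgE cells. It was at 8.86 ± 1.48 in IgE PC against 3.18 ± 0.15 in IgE GC cells (5.69, adjusted p = 3.57e-07). The source of that signal was not tested. The neutrophil and eosinophil list was called in IgG1 cells (1 of 6 higher, adjusted p = 0.037, and adjusted p = 0.22 with an estimated correlation), a call lost after quantile normalization (0.053) and without GFP-positive GC replicate 1 or 2 or PC replicate 1 (0.054 to 0.16). Thy1 in IgG1 cells lost its call without PC replicate 2 (adjusted p = 0.08). T cell and macrophage lists passed as higher in IgG1 cells without PC replicate 1 (0.022 and 0.044). BCL2 family, migration, MYC target, oxidative phosphorylation, immediate early, natural killer, basophil and stromal lists were not called in either isotype, nor the dark zone list in IgG1 cells (1 of 7 lower). MYC targets in IgE cells had a median of -0.11 with a mean of 0.05, and stromal markers 0.15 with -0.02 (0.08 and -0.03 in IgG1 cells).

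Over 12098 genes the changes in both isotypes correlated at r = 0.862 (rho = 0.74) across genes, which are not independent replicates, and the comparisons share no arrays. Of the called genes 789 were higher and 1074 lower in both, where independent lists would share 103 and 213, and 3 were called with opposite sign. Of the 2860 genes called for IgE, 2785 (97.4%) had the same sign for IgG1.

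**Figure D3:**
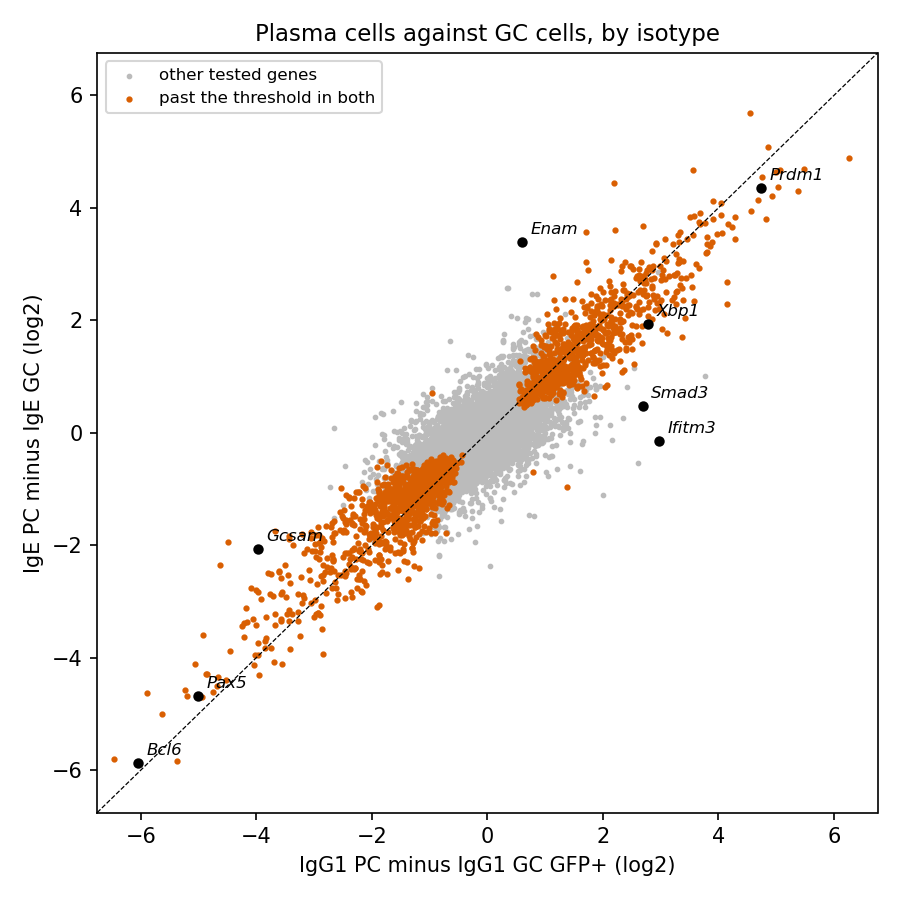
Log2 difference between plasma cells and GC cells in IgG1 (horizontal axis) and IgE cells (vertical axis), with 1 point per tested gene (12098), orange for genes past the threshold in both, black for 8 named genes and a dashed line of equality. Bcl6 lies at -6.05 for IgG1 and -5.87 for IgE, and Prdm1 at 4.74 and 4.35.

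IgE and IgG1 plasma cells were compared directly, with 4 arrays against 2. Whether an array of either group was lost or relabelled was not tested, and a relabelled array would change the calls below. Enam, the enamelin gene, was at 7.10 ± 0.18 in IgE (SD, n = 4) and 4.15 ± 0.61 in IgG1 PC (n = 2), a log2 difference of 2.96 (SE 0.29, adjusted p = 5.9e-05). Gcsam was at 8.35 ± 0.23 against 5.86 ± 0.52 (2.48, adjusted p = 3.42e-05), Tnfrsf17, the receptor for survival factors of plasma cells, at 9.58 ± 0.08 against 6.76 ± 1.21 (2.82, adjusted p = 0.000408), and Fcer2a, the low-affinity IgE receptor, at 9.22 ± 0.51 against 6.68 ± 1.18 (2.55, adjusted p = 0.00161). Lower in IgE PC were Ifitm3, an interferon-induced membrane protein (4.00 ± 0.46 against 7.45 ± 0.11, -3.46, adjusted p = 1.85e-05), and Smad3, a mediator of TGF-beta signals (6.59 ± 0.40 against 8.82 ± 0.04, -2.23, adjusted p = 5.9e-05). The plasma cell regulators Prdm1 (0.29, adjusted p = 0.781), Xbp1 (-0.33, adjusted p = 0.672) and Irf4 (0.09) were not called.

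In limma 116 genes differed between the plasma cells, 95 higher and 21 lower in IgE PC, and after a further quantile normalization 60 and 24. The count depended on the IgG1 pair. It was 252 without IgG1 PC replicate 1 (72 of the 116 kept) and 103 without replicate 2 (40 kept), where the lone array is assumed to vary like the other groups, and 76 without IgE PC replicate 1. It was 2 with only these groups in the fit, 46 with array weights and 227 without the 2 arrays that stood apart. NF-kB genes were higher in IgE PC at the preset correlation (13 of 14 above 0, median 0.39, adjusted p = 0.00026, and adjusted p = 0.28 with an estimated correlation), with Rel (1.22) and Nfkbie (1.29) called over all genes and 4 over the list alone. Without IgG1 PC replicate 2 these were 1.04 and 1.05 and not called. B cell identity genes were higher too (16 of 20 above 0, median 0.35, adjusted p = 0.00073, and adjusted p = 0.28 with an estimated correlation), with 2 called, and 6 over the list alone. At the preset both list calls stood whichever array was left out. The secretory list was higher (33 of 37 above 0, median 0.22, adjusted p = 0.0065), with the chaperone gene Hyou1 called (0.77, a call lost without IgG1 PC replicate 2 or any 1 of the IgE PC arrays) and 2 over the list alone. The list call was lost without IgG1 PC replicate 2 (0.12, adjusted p = 0.47) and with an estimated correlation (adjusted p = 0.75).

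No other list was called between the plasma cells, but several passed in other settings, given here with the list median in brackets. The G1/S list (median 0.00, adjusted p = 0.89) passed as lower without IgG1 PC replicate 1 (-0.30) and as higher without replicate 2 (0.43). G2/M passed as lower without IgG1 PC replicate 1 (-0.30) or IgE PC replicate 3 (-0.23), and T cell markers without IgG1 PC replicate 1 (-0.36). MHC class II (0.44) and light zone genes (0.31) passed as higher without IgG1 PC replicate 2, and light zone genes also without IgE PC replicate 2 (0.22). After quantile normalization light zone genes passed as higher and G2/M as lower (adjusted p = 0.029 each). Immediate early genes passed as lower without IgG1 PC replicate 2 (-0.33) or IgE PC replicate 1 (-0.28), and neutrophil markers without IgG1 PC replicate 2 (-0.35) or IgE PC replicate 4 (-0.44). The list median, mean and test differed in sign for the plasma cell (0.09, 0.11, tested lower), stromal (0.08, -0.05, lower), migration (-0.05, 0.04, lower) and macrophage lists (-0.10, 0.03, lower), none of them called.

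**Figure D4:**
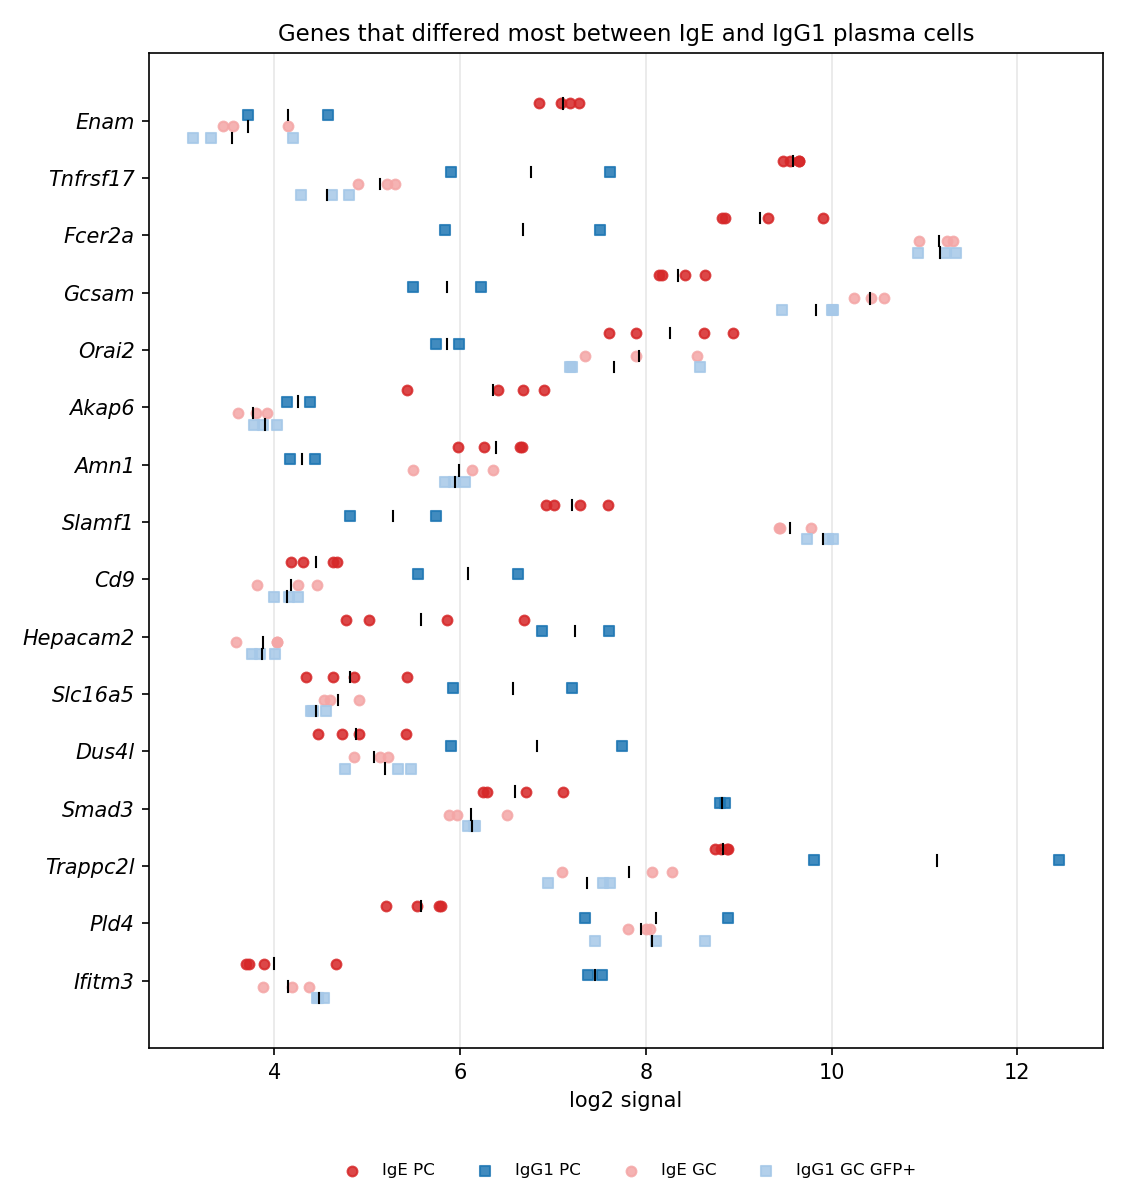
Log2 signal (horizontal axis) of the 8 genes most raised and the 8 most lowered in IgE against IgG1 plasma cells (vertical axis), in IgE PC (n = 4), IgG1 PC (n = 2), IgE GC (n = 3) and GFP-positive IgG1 GC cells (n = 3) by colour and shape, with 1 marker per array and a tick at each group mean. Enam had a mean of 7.10 in IgE PC and 4.15 in IgG1 PC, and Ifitm3 of 4.00 and 7.45.

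Whether the change from GC to plasma cell differed by isotype was tested as an interaction, in which 11 genes passed in limma. The log2 change in IgE minus that in IgG1 cells was positive for Enam (2.79), the cationic amino acid transporter gene Slc7a3 (2.23), Amn1 (2.03), the proton channel gene Hvcn1 (1.92), Gcsam (1.90), Samsn1 (1.52), Cilk1 (1.48) and the autophagy kinase gene Ulk2 (1.38). It was negative for Ifitm3 (-3.12), Isoc1 (-2.35) and Smad3 (-2.22). Xbp1 was not called. Ifitm3 and Smad3 kept the call whichever array was left out, and among those repeats Enam lost it without IgE GC replicate 2. The count ranged with the arrays, at 34 and 32 without IgG1 PC replicates 2 and 1, 2 to 5 without any 1 of the IgE GC arrays, 3, 7 and 5 without GFP-positive IgG1 GC replicates 1, 2 and 3, and 4 without IgE PC replicate 4. It was 1 with only these groups in the fit and 17 with array weights.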

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

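In this part, the tests of GC cell carry-over, of the signal distribution and of a single IgG1 PC array, and the list tests without single arrays, were chosen only after the result was seen, while the test of plasma cell carry-over was chosen before.

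Differences between isotypes in the step from GC to plasma cell were tested as an interaction. It passed for Enam (2.79), Slc7a3 (2.23), Amn1 (2.03), Hvcn1 (1.92), Gcsam (1.90), Samsn1 (1.52), Cilk1 (1.48) and Ulk2 (1.38), where the log2 change in IgE minus that in IgG1 cells was positive, and for Smad3 (-2.22), Isoc1 (-2.35) and Ifitm3 (-3.12), where it was negative. Among lists it passed as higher for the NF-kB and CD40 response (median 0.68, 14 of 14 genes above 0, adjusted p = 2.4e-07, and adjusted p = 0.088 with an estimated correlation), B cell identity (0.48, 15 of 20, adjusted p = 0.00072 and 0.23) and light zone genes (0.37, 18 of 23, adjusted p = 0.00072 and 0.27). As lower it passed for G2/M (-0.22, 3 of 28 above 0, adjusted p = 0.00072 and 0.48), T cell markers (-0.35, 0 of 9, adjusted p = 0.0025 and 0.23) and the plasma cell programme (-0.38, 3 of 14, adjusted p = 0.013 and 0.48), the second value of each pair being the adjusted p with an estimated correlation. NF-kB and B cell identity kept the call whichever array was left out. The plasma cell call was lost without IgE GC replicate 3 (-0.23, adjusted p = 0.2) or IgG1 PC replicate 1 (-0.31, adjusted p = 0.94), light zone without IgG1 PC replicate 1 (0.057), and G2/M (-0.09, adjusted p = 0.28) and T cell markers (-0.25, adjusted p = 0.13) without IgG1 PC replicate 2. Lists without a call on all arrays gained one when an array was left out. As lower these were G1/S in 4 repeats, most strongly without IgG1 PC replicate 1 (-0.55, adjusted p = 0.00017), dark zone without IgE GC replicate 1 (0.019) or IgG1 PC replicate 1 (0.047), oxidative phosphorylation without GFP-positive IgG1 GC replicate 2 (0.026) or IgE PC replicate 3 (0.043), immediate early without IgG1 PC replicate 2 (0.026) or IgE PC replicate 1 (0.039), neutrophil without GFP-positive IgG1 GC replicate 3 (0.047) or IgE PC replicate 4 (0.032), and natural killer without IgG1 PC replicate 1 (0.039). As higher they were MHC class II without IgG1 PC replicate 2 (0.012) or GFP-positive IgG1 GC replicate 3 (0.047), and MYC targets without IgG1 PC replicate 2 (0.019) or IgE PC replicate 4 (0.045).

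Among the 4 IgE PC arrays, a few values stood apart from the other arrays of that group. Replicate 2 had the highest MHC class II list mean, at 8.81 against 8.23 to 8.30, and replicate 1 the highest T cell list mean, at 5.81 against 5.76. Replicate 1 also had the lowest mean of the dark zone list, at 8.55 against 8.84 to 8.90. For single genes, Brca1 was lowest in replicate 1 (6.22 against 7.15 to 7.24), Cd4 highest in replicate 2 (5.27 against 4.96 to 4.99), Cd86 highest in replicate 2 (5.90 against 4.26 to 4.35), Plk1 highest in replicate 3 (9.52 against 9.15 to 9.20) and Samsn1 highest in replicate 3 (9.61 against 9.33 to 9.37). These were 3 of 24 list means and 5 of 150 genes, where chance alone gives about 1.2 and 7.5.

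The higher plasma cell programme in IgE GC cells was weighed against plasma cell carry-over, though the CD138-negative gate should remove such cells. Carried-over cells would bring every plasma cell gene at 1 share. Of 27 genes at least 16-fold higher in IgE PC, 23 had a share above 0. The median share was 1.5% (quartiles 0.66 and 2.55), and 5 genes (18.5%) differed from it by more than 2 SE. For several genes the SE was near the size of the share, as for Derl3 (3.46%, SE 2.87). Selenom, at -1.33% (SE 1.84), did not count as different, while Trav14-1, with a small SE, did (0.17%, SE 0.09). With such SE the count could hardly reject 1 share, so it does not speak for carry-over. The 214 genes at least 4-fold lower in IgE PC could not test a share of 1.5% either. The -0.022 it would bring is small beside the SE (median log2 difference 0.03, SE 0.08). Carry-over may account for part of the pattern, most of all in replicate 3 (share 2.45% against 0.55 and 0.65), and an early plasma cell programme in IgE GC cells stayed open and was not tested.

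The 95 genes higher in IgE than in IgG1 plasma cells were weighed against carry-over of GC cells into the CD138-positive gate. For 72 of them, with a higher IgE GC level, it would take a median share of 66.99%, and 23 had an IgE GC level at or below that of IgG1 PC. The share read from 26 other genes at least 16-fold higher in GC cells was 1.32% (highest array 2.81), and 1.47% with the raised ones among them, so that carry-over is unlikely as the whole cause.

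Other technical sources for the 116 genes were the signal distribution of the IgG1 PC arrays, with a lower upper quartile (7.01 and 6.96 against 7.08 to 7.12 in IgE PC) at similar medians (5.35 each against 5.31 to 5.36), and a single array. With 1 distribution for all arrays 80 of 116 stayed past the threshold, which argues against the distribution as the main source. Without IgG1 PC replicate 2, 40 stayed past it (72 without replicate 1), and the median absolute log2 difference was 1.17 (1.35 without replicate 1) against 1.32, with 114 of 116 of the same sign in both repeats. Which genes passed could thus depend on 1 array, where fewer arrays also weaken the test, and a biological difference between the isotypes remained among the open explanations.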

How the results depend on the processing

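Array weights, the fit without the 2 arrays that stood apart and the list tests with the block were chosen only after the results were seen, the other settings below before. No call of a named gene turned its direction in any setting, while DZ against LZ changed from 433 higher and 331 lower genes to 356 and 410 after a further quantile normalization. Of the repeats for named genes 4564 stayed on their side of the threshold, 228 lost and 2 gained the call. A minimum of 2-fold, which can only shorten a list, left 1630 genes for IgE PC against IgE GC, 1621 for IgG1 GC and 1762 for IgE GC against naive, and 102 for DZ against LZ. With array weights the counts were 1 for IgE GC against GFP-negative IgG1 GC, 46 for IgE PC against IgG1 PC (all 46 among the 116) and 17 for the interaction of isotype and cell stage (9 of the 11 kept). With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, the counts were 1 for GFP-positive against GFP-negative IgG1 GC, 2 for IgE PC against IgG1 PC, 1 for the interaction, 1524 for IgG1 GC and 2049 for IgE GC against naive. The count rose to 3280 for IgE PC against IgE GC, from 2860. Group sizes and spreads differ between the comparisons, so this rise does not tell whether fewer arrays account for the lower counts. Whether the shared spread was too small for the naive and IgG1 PC arrays, which correlated least within their groups, or too large for the GC arrays was not tested. Without the 2 arrays that stood apart, IgE PC against IgG1 PC gave 227 (all 116 kept). The cause of these changes was not tested.

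With the replicate number as a block, IgE PC against IgG1 PC gave 72 genes (60 of the 116 kept) and the interaction 5 (4 of 11 kept), though those groups did not pass the pairing limit. Between the plasma cells the MHC class II list then passed as higher (adjusted p = 0.025) and the G2/M (adjusted p = 0.019) and neutrophil lists (adjusted p = 0.0095) as lower, and against GFP-negative IgG1 GC cells immediate early genes passed as lower in IgE GC cells (adjusted p = 0.046). The interaction of isotype and cell stage gained MHC class II (adjusted p = 0.02) and MYC targets (adjusted p = 0.036) as higher and dark zone (adjusted p = 0.036) and neutrophil lists (adjusted p = 0.02) as lower. Stromal markers passed as lower in IgG1 GC against naive cells (adjusted p = 0.036), receptor signalling as lower in GFP-positive against GFP-negative IgG1 GC cells (adjusted p = 0.041), and the plasma cell list lost its call between the zones (adjusted p = 0.058). The other counts stayed within 1.5 times with the block (802 for DZ against LZ, with 683 of the main calls kept), and the paired GFP-positive and GFP-negative IgG1 GC cells stayed at 0.

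With each array left out in turn, the counts ranged from 76 to 252 for IgE PC against IgG1 PC, from 2 to 34 for the interaction, from 479 to 815 for DZ against LZ, from 2003 to 3434 and from 2293 to 4008 for IgG1 and IgE GC against naive, and from 2181 to 2641 and 2024 to 2481 for IgE and IgG1 PC against GC. The 5 counts of 0 stayed at 0. The DZ signature in IgE GC cells ranged from 0.134 to 0.267 and the LZ signature from -0.132 to -0.003. Signal near the floor limits the fold of dim genes, and the median half-width of the 95% interval was 1.41-fold for GC comparisons, 1.44-fold between plasma cells and 1.22-fold between zones.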

Other observations

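In this part, the splits for the zone signatures and for the interaction of zone and GFP, and the exact permutation tests, were chosen only after the result was seen, and the other splits before.

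Plasma cells also differed from GC cells in heavy chain genes of other isotypes and in single homing and survival genes. Igha rose by 2.91 in IgE and 2.62 in IgG1 cells and Ighg3 by 3.45 and 4.28. Ighg3 varied widely, with an SD of 1.31 in IgG1 PC (n = 2) and 1.53 in GFP-positive IgG1 GC cells (n = 3). The epsilon and gamma-1 genes were not analysed, and whether these signals came from cells of the sorted isotype was not tested. In IgE PC against IgE GC cells the selectin ligand gene Selplg (3.04), the chemokine receptor Ccr10 (2.50) and the integrin subunit Itga4 (2.31) rose. In IgG1 cells Cd28 (5.38), which sustains long-lived plasma cells, the adhesion receptor Cd93 (4.94) and the survival gene Bcl2l1 (1.84) rose, and Cd40 (-2.70) fell. All 7 of these genes also passed in the same direction in the other isotype, which was looked up after the values were seen, with Bcl2l1 at 0.66 in IgE cells (adjusted p = 0.0392). Between the plasma cells Bcl2l1 was lower in IgE than in IgG1 (-1.25, adjusted p = 0.0242), a call lost without any 1 of IgG1 PC replicate 1 or 2 or IgE PC replicate 1 or 2.

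List means of the 9 GC arrays were compared by exact permutation, which treats them as independent although the GFP-positive and GFP-negative IgG1 arrays paired by number (0.109 to 0.154). IgE arrays also matched best with the GFP-negative IgG1 arrays of equal number (0.095 to 0.14). IgE arrays against all 6 IgG1 arrays gave an exact p of 0.0238 for the NF-kB (mean difference -0.23), secretory (0.28) and macrophage lists (0.23), 0.0357 for the plasma cell list (0.31) and 0.0476 for G1/S (0.19), where 0.0119 is the smallest possible. None passed the correction over lists (smallest adjusted p 0.19). For the NF-kB and macrophage lists all 3 IgE arrays lay beyond all 6 IgG1 arrays.

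Other splits of the same arrays were fitted for the 9 counts whose groups all had at least 3 arrays. For DZ against LZ 1 of 100 splits drawn with a fixed seed, the real one, gave 764 genes, and the highest other gave 3. For IgE PC against IgE GC 1 of 35, the real one, gave 2860, and the highest other 1079. In both, a share under 0.05 of the splits gave as many genes, which makes chance unlikely without excluding it. The splits for DZ against LZ were drawn from 200 possible ones and took no account of replicate numbers. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts there were 2813 and 73 for IgG1 GC against naive (1 of 10 splits as large) and 3230 and 1 for IgE GC against naive (1 of 10). Where the real count was 0 every split gives at least as many, so the splits tell nothing about chance there. This held for GFP in the zones and the interaction of zone and GFP (100 of 100 splits, highest other 1 in each), and for IgE GC against GFP-positive and GFP-negative IgG1 GC and GFP-positive against GFP-negative cells (10 of 10, highest other 0 in each). For the signatures 3 of 10 splits gave a median as far from 0 as the DZ value of 0.19 (farthest other -0.26), and 4 of 10 as the LZ value of -0.09 (farthest other 0.18).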
